A study of Mus musculus with 8 samples.

How the data were processed

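The samples were 8 pools of wild-type mouse embryos at 5 stages from embryonic day 6.5 to 8.5. Per the labels' protocols, oocytes of B6D2F1 females were fertilised by injection of sperm from B6/CAST F1 males, and the embryos developed in surrogate females. Outer extraembryonic tissues were kept where possible, embryos of a stage were pooled and dissociated, and libraries were made with 10x Genomics 3' chemistry (version 2). The description of 1 day 8.5 library names day 8.0, while its title and stage label give day 8.5, and no result here depends on it because the table has no column per library. Per the submitters' processing notes, reads were aligned and counted with Cell Ranger (version not given) on the mouse genome build mm10.

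The deposited score in the table is the centre of each cell state (a cluster of cells) for each gene, per the file headers. The sources used here do not state how the authors normalised the counts, removed doublets, clustered the cells or chose the genes, nor whether the scores are logarithms and to which base. The unit was therefore kept as deposited, differences between states were taken by subtraction, and no fold changes are given. None of the 42 columns names a library, and they were taken to pool all libraries. No sample therefore entered as a replicate, and no test, SD between samples or p-value was possible. The labels give a minimum read depth for the libraries but neither cells nor reads per state, so the precision of a score is unknown. Low scores in particular may rest on few reads, and differences under 0.5 were not counted. Gene positions came from GENCODE M21 (GRCm38), in which 704 of the 712 genes were found, 38 of them on chromosome X and none on Y.

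Lists of markers for 25 cell types and 31 further gene groups, most of the comparisons and the rule for naming genes were fixed before the data were examined. That rule named up to 5 genes per state by the difference from the mean of all other states, up to 10 genes per direction of a comparison, and measured members of the fixed lists. Each gene was standardised over the 42 states, and a state's score for a list was the median over the measured members. A state took the name of its best list if the list had at least 4 measured members, at least 3 of them lay over 1 SD above their mean, and at least 1 was among the 10 leading genes of the state with no other list having more. The score was also placed among 10000 random lists matched on mean level in 10 bins (seed 1). The details of this naming rule, the threshold of 0.5 and the limit of 0.25 for low Xist were set after the values had been seen. The test of sex as a cause of low Xist was written on the median correlation, which passed its limit, while the code first decided on the lowest pair and then, after that outcome, on the median. It was finally treated as undecided whatever its value, because shared effects of sex on autosomal genes would give the same, as was the test of lower detection, because of the unknown normalisation. The test of free visceral endoderm RNA was also set to undecided after its outcome, because its genes did not all vary together, and so was the test of a single globin source, because its globin pairs differed. A class's markers named its states, so their counts in a comparison of that class follow partly from the naming. Many gene groups share members with these marker lists, such as the sarcomere, plasma protein, basement membrane, globin, Cdx, pluripotency, and somite clock and Notch groups. Counts and peaks of such a group in the class concerned therefore also follow partly from the naming.

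A gene was counted in a comparison when the mean difference between the classes reached 0.5 and the ranges of their states did not overlap. Because no state took the primitive streak or allantois name, the comparisons of epiblast with nascent mesoderm, of presomitic with nascent mesoderm and of extraembryonic mesoderm with state 5 were added after the states had been named. The comparisons within the heart tube-like and node-like classes were added because their states stood far apart. Similarity was the Pearson correlation across gene-centred levels, with an average-linkage tree. Alternatives covered the list score, the reference for leading genes, the correlation, the linkage, the genes used, the threshold and the centring of states, and their effect is given in the closing section. Ranges in brackets beside the correlation with transcript length are 95% confidence intervals from 1000 bootstraps over genes, which describe spread among genes and not among embryos.

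The code was tested on simulated data. In 20 tables with shuffled values the naming rule named 29 of 840 states (3.45%). Each gene was shuffled separately, which removes the correlation between genes, so this share is not a rate of false names for the real values. Of 460 marker lists planted in such tables, all had the best score in their state, 330 (71.7%) passed the naming rule and none was given another name, so the rule leaves some true likenesses unnamed. Of planted differences of 0.6 with noise of SD 0.05, 92.5% were counted, and no unmoved gene was. That noise was chosen freely and is unrelated to the unknown precision of the scores, so this checks the code only. The rule on overlapping ranges was not part of it. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.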

Results

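Wild-type mouse embryos were dissociated and profiled by droplet-based single-cell RNA sequencing between embryonic days 6.5 and 8.5, the span of gastrulation and early organ formation. The 8 libraries covered 5 stages, with 1 library each at day 6.5 (10 pooled embryos) and day 7.0 (9 embryos), 2 at day 7.5 (7 and 4 embryos), 2 at day 8.0 and 2 at day 8.5 (10 embryos each). The deposited table holds 1 value, called the level here, for each of 712 genes in each of 42 numbered cell states. Its headers name no library, so the states were taken to pool all libraries. It carries no stage, no cell number and no depth per state, and no value has a replicate error. Levels ran from 0 to 1.79 with a median of 0.051, and 1.8% of the 29904 values were 0. Differences between states are therefore given as differences in level, with no test, and a gene was counted as higher or lower when the difference reached 0.5 and the states of both classes did not overlap.

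The series presents the table as a reference map of cell states, and the question of which cell type each state resembles was addressed with marker lists. Of the 42 states, 36 took the name of a list and 6 stayed unnamed (states 2, 5, 11, 12, 20 and 24). The 36 fell into 21 classes, each of which is named for its likeness to a tissue. Extraembryonic classes were extraembryonic ectoderm-like (states 0 and 25), differentiated trophoblast-like (28), visceral endoderm-like (4, 29 and 40), parietal endoderm-like (14) and extraembryonic mesoderm-like (15 and 41). Epiblast-like states numbered 4 (3, 8, 17 and 19), and state 27 was primordial germ cell-like. State 3 scored nearly as high for the primitive streak list (1.42) as for the epiblast list (1.63). Mesoderm classes were nascent mesoderm-like (37), presomitic mesoderm-like (30), somite-like (18), pharyngeal mesoderm-like (34), heart tube-like (6 and 21), endothelium-like with blood progenitors (13, 32 and 36) and primitive blood-like (9 and 22). The axial and ectodermal classes were neuromesodermal progenitor-like (26 and 31), node and notochord-like (23 and 38), forebrain and midbrain-like (1), hindbrain and spinal cord-like (39), neural crest-like (33 and 35) and surface ectoderm-like (10 and 16), and state 7 was gut endoderm-like. No state took the primitive streak or lateral plate name, and the allantois and preplacodal lists, with 3 measured markers each, could give none. List scores of the named states ran from 1.44 in surface ectoderm-like state 16 to 5.51 in heart tube-like state 21, and every score lay at or above percentile 99.9 of random lists matched on mean level. The list had been chosen for its high score, so a high percentile was built in and is no evidence for a name. The best lists of unnamed states 2 and 20 lay at percentile 100, and that of unnamed state 12 at 99.55.

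**Figure D1:**
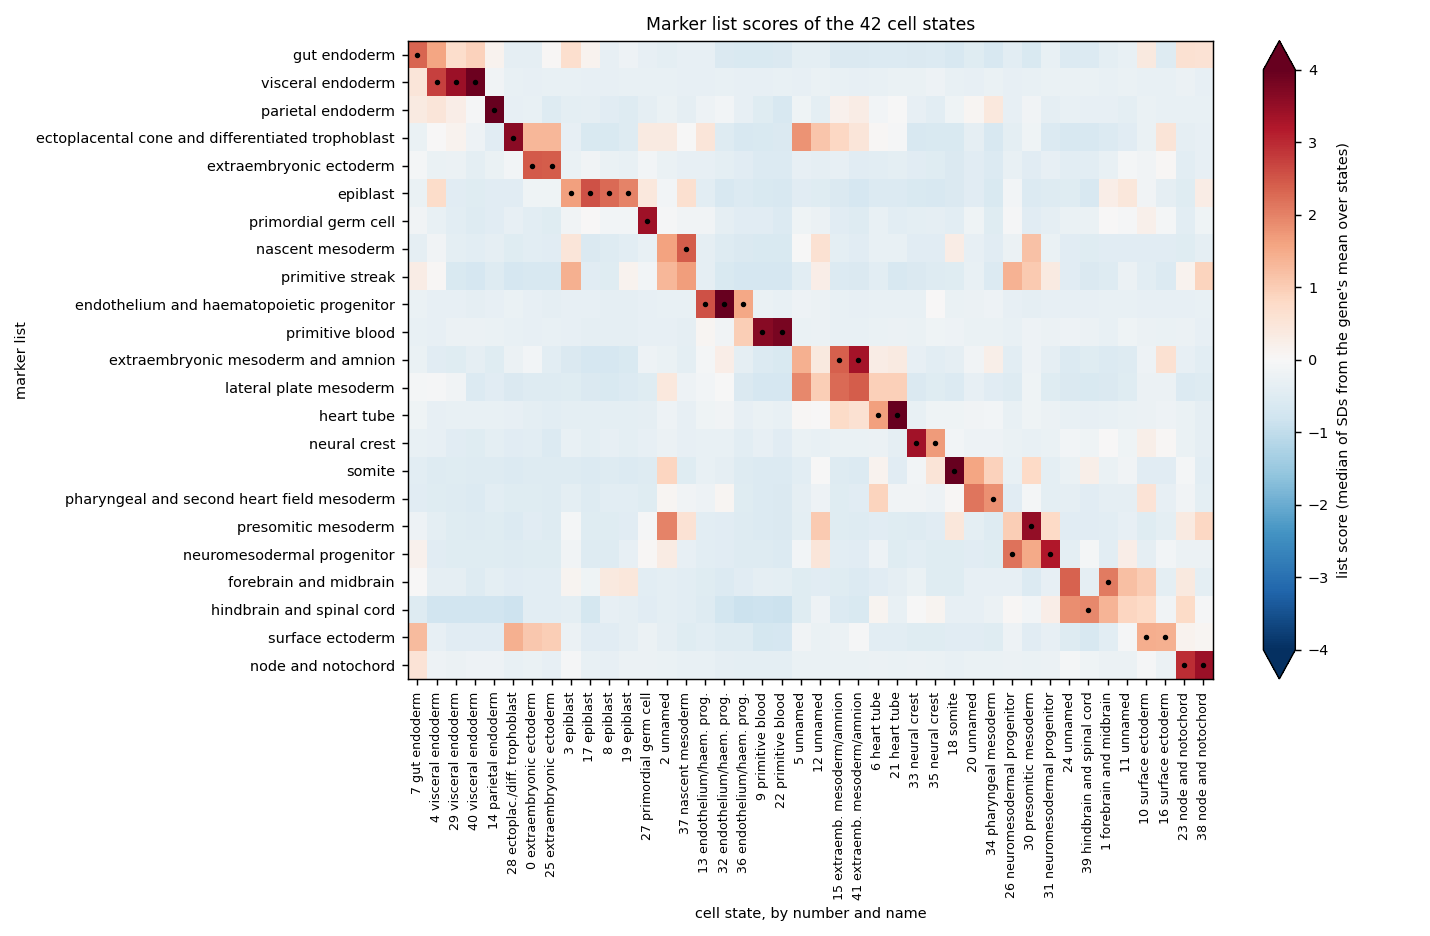
Score of each marker list with at least 4 measured genes (rows) in each of the 42 cell states (columns, ordered by an average-linkage tree), as the median over its genes of the distance from the gene's mean over states in SDs. A black dot marks the list that named the state, 36 in all, with scores between 1.44 and 5.51.

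The leading genes differed between classes. In heart tube-like state 21 the sarcomere gene Actc1 reached 1.67 against a mean of 0.12 over the other 41 states, and Myl7 reached 1.75 against 0.22. In parietal endoderm-like state 14, Srgn (1.38 against 0.041), the laminin gene Lama1 (1.35 against 0.072) and the type IV collagen gene Col4a2 (1.46 against 0.19) led. Node-like state 38 was led by Tppp3 (1.24 against 0.024) and Fam183b (1.19 against 0.017). Primordial germ cell-like state 27 was led by Ifitm3 (1.33 against 0.22), and the germ cell gene Dppa3 stood at 0.76 against 0.0037. Etv2, a transcription factor of the endothelial and blood lineages, led state 13 (0.96 against 0.13), and Plvap and Cldn5, of vessel walls, led state 32 with Plvap at 1.04 against 0.048 and Cldn5 at 1.00 (mean of the others 0.029). State 36, which took the same class name, was led by Tgfb1 at 0.87 and held the platelet and leukocyte genes Fermt3 at 0.73 and Plek at 0.67. Differentiated trophoblast-like state 28 was led by Plac1 (1.27 against 0.11), and its name rests on 4 measured markers. Neural crest-like state 33 had Crabp1 at 1.31 and Tfap2b at 0.62, and in state 35 these were 1.33 and 0.39. Over all states, 892 combinations of gene and state lay at least 0.5 above the mean of the other states. Against the next highest state instead, only 88 did and 30 states had none.

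Closely related states were common in the map. Across genes, 12 states correlated above 0.9 with their nearest state, the median of the nearest correlations was 0.744, and 15 pairs were each other's nearest state. The closest were primitive blood-like states 9 and 22 (r = 0.985), visceral endoderm-like states 29 and 40 (0.972) and extraembryonic ectoderm-like states 0 and 25 (0.957). Parietal endoderm-like state 14 stood furthest apart, with its nearest state, visceral endoderm-like state 29, at r = 0.252. Primordial germ cell-like state 27 was nearest to unnamed state 2, at r = 0.288. In the nearest-state pairs of the 4 states with Xist below 0.25, the gene with the largest of all differences was Xist, the RNA that silences an X chromosome in female cells (chromosome X, 103460366 to 103483254). The states were picked for low Xist at a limit set after the values had been seen, so a large difference is partly built in. In states 25 and 0 it was under 0.5 (-0.46). State 12, just above the limit at 0.30 and nearest to state 30 at 1.04, was left out of these pairs. Xist was at 0.13 in extraembryonic ectoderm-like state 25 and 0.60 in state 0, at 0.15 in epiblast-like state 19 and 0.91 in state 8, at 0.18 in neural crest-like state 35 and 1.04 in state 33, and at 0.18 in unnamed state 11 and 0.75 in forebrain and midbrain-like state 1. These correlations are across genes, which are not independent replicates.

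**Figure D2:**
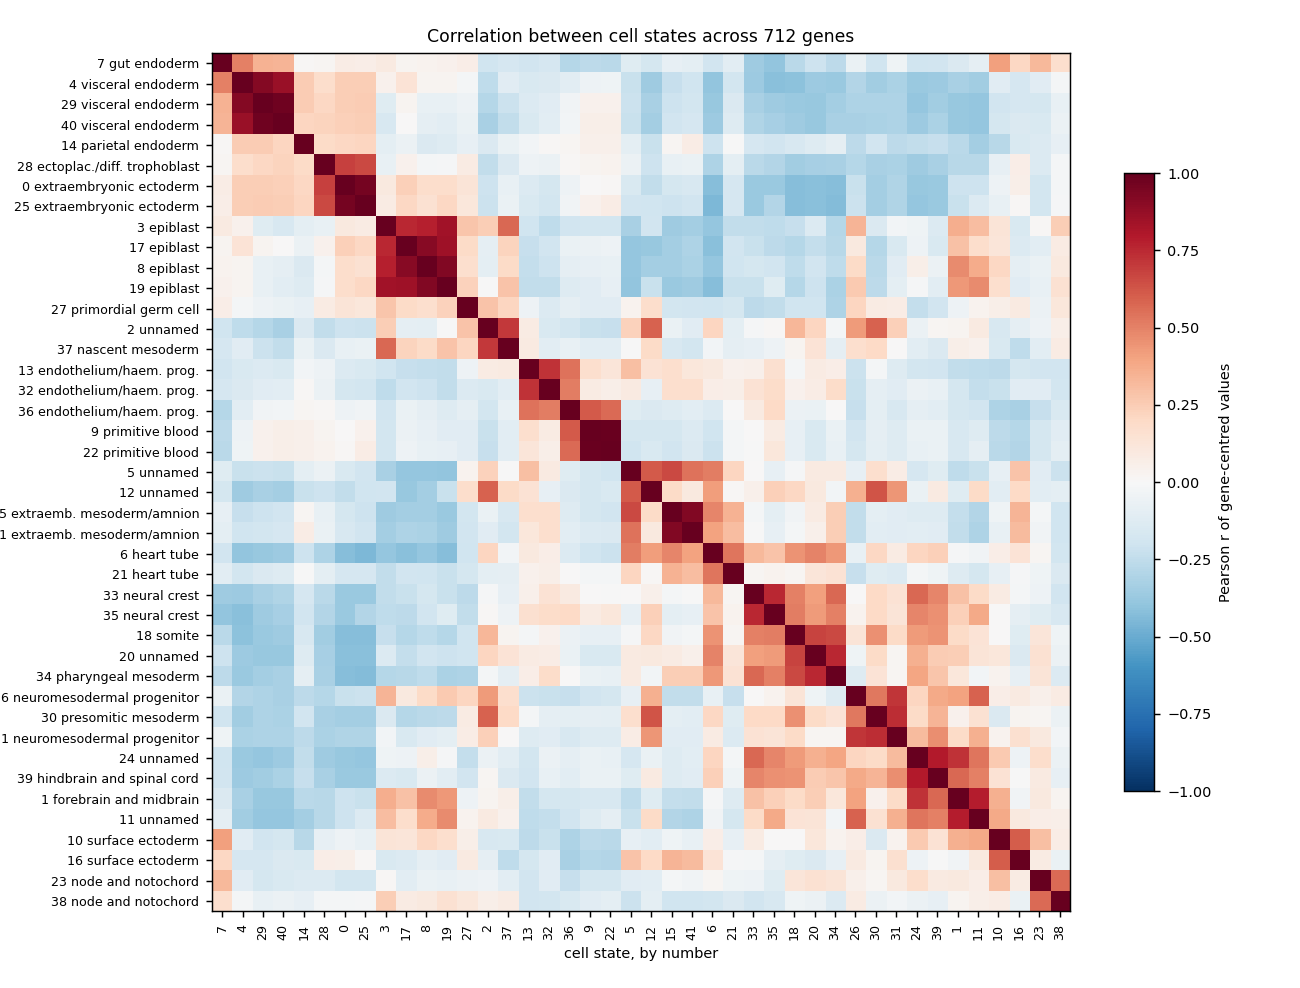
Pearson correlation between every 2 of the 42 cell states across 712 gene-centred levels, with states on both axes in the order of an average-linkage tree. Blocks of high correlation join the blood-like states 9 and 22 (r = 0.985) and the visceral endoderm-like states 29 and 40 (r = 0.972), while parietal endoderm-like state 14 stands alone.

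**Figure D3:**
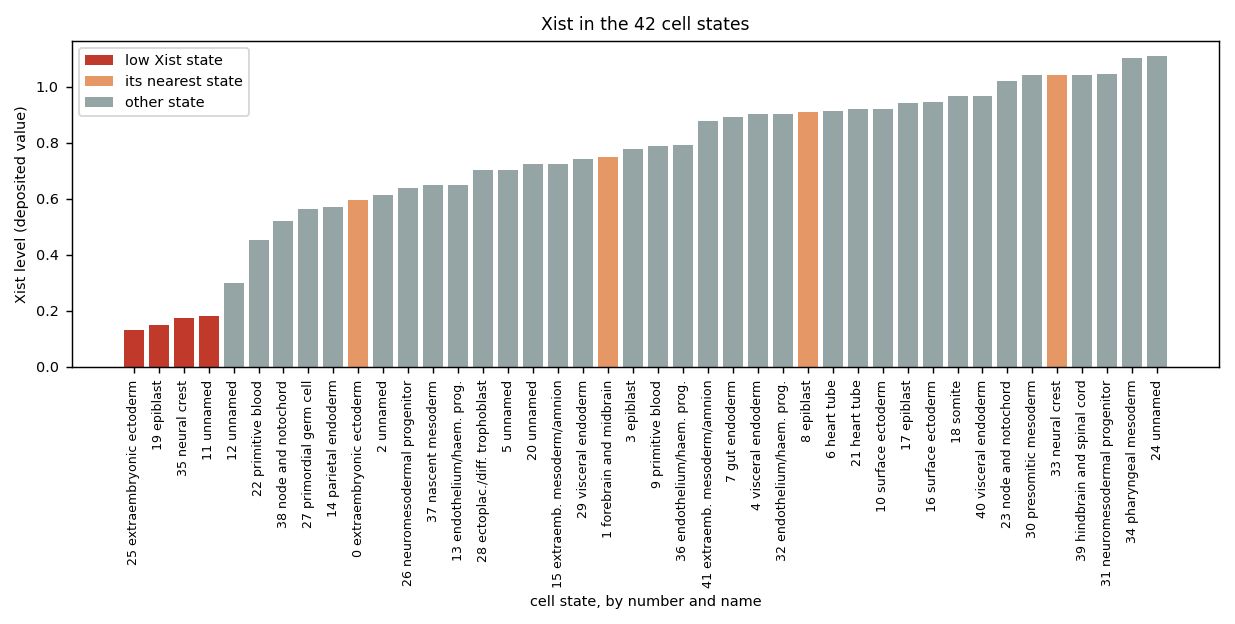
Level of Xist (vertical axis, the deposited value) in each of the 42 cell states, sorted. Dark red bars are the 4 states below 0.25 and orange bars are the nearest state of each, which lie between 0.60 and 1.04.

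Visceral endoderm-like states were higher than gut endoderm-like state 7 in many plasma protein and uptake genes, although state 7 also held Ttr at 1.11 and Rbp4 at 0.98. The apolipoprotein genes Apoa2 (mean 1.19 over the 3 visceral states, range 0.73 to 1.57, against 0.11 in state 7), Apoa4 (1.12 against 0.13) and Apob (1.17 against 0.25) were higher, as were Cubn (1.17 against 0.094) and Amn (1.21 against 0.38), which form the cubam receptor for protein uptake, and its adaptor Dab2 (1.27 against 0.44). Gut endoderm-like state 7 was higher in Trh (1.21 against 0.24), Apela (0.99 against 0.061), a peptide ligand of the apelin receptor, Ifitm1 (1.13 against 0.26), Krt19 (0.92 against 0.28) and Cd24a (1.17 against 0.54). Of the measured plasma protein genes 11 of 14 were higher in the visceral states and none in state 7, and of the endocytosis genes 4 of 7. The visceral endoderm markers that named the states, which are not independent evidence, were higher in 9 of 11. Many of the plasma protein genes, such as Apoa4, Apob, Apom and Afp, are themselves among these markers. So are the endocytosis genes Cubn and Amn, and the counts of both groups follow partly from the naming. In all 36 genes were higher in the visceral states and 16 in state 7, or 15 in total at a threshold of 0.75, and the differences of all genes had an SD of 0.252. The share higher in the visceral states was 69.2%, and 81.0% after each state was centred on its median.

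Parietal endoderm-like state 14 differed more from the visceral states than the gut endoderm-like state did. It held the basement membrane genes of Reichert's membrane at high levels, and all 5 measured members were higher there, such as Lama1 (1.35 against a mean of 0.17), Lamc1 (1.38 against 0.26), Nid1 (1.16 against 0.075) and Col4a2 (1.46 against 0.51). Lama1, Lamc1, Nid1 and Col4a2 are also markers that named state 14, so this count follows partly from the naming. Fst, which encodes the activin antagonist follistatin, showed the largest difference (1.45 against 0.076; chromosome 13, 114452290 to 114458951), and Cryab (1.12 against 0.023) and Srgn (1.38 against 0.27) were also higher. Plasma protein genes were lower in 13 of 14 cases, among them Apom (0.16 against 1.43), the retinol and thyroxine carriers Rbp4 (0.34 against 1.58) and Ttr (0.46 against 1.70; chromosome 18, 20665280 to 20674321) and the fetal albumin gene Afp (0.078 against 1.20). Of the 7 endocytosis genes 6 were lower. In all 35 genes were higher in state 14 and 58 in the visceral states, 46 in total at 0.75 (SD of all differences 0.317).

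Within the trophoblast lineage, extraembryonic ectoderm-like states 0 and 25 were higher than differentiated trophoblast-like state 28 in Gm1673 (0.82 against 0.13), Ddah1 (0.93 against 0.31), Cited1 (0.85 against 0.23), Apoc1 (0.72 against 0.11) and the signalling ligand gene Wnt6 (0.55 against 0.022). State 28 was higher in Plac1 (1.27 against 0.092), an X-linked gene of the placenta, Ldoc1 (1.18 against 0.26), Lgals3 (1.09 against 0.24), the keratin gene Krt7 (0.91 against 0.080), the secretin gene Sct (0.91 against 0.095) and Plet1 (1.21 against 0.43). Of 11 genes of keratins and simple epithelium, 3 were higher in state 28 and 1 in the extraembryonic ectoderm-like states. The totals were 10 and 17 genes, or 7 in all at 0.75 (SD of all differences 0.183). State 28 took the extraembryonic ectoderm name when only markers of a single list were used.

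At the onset of gastrulation, the epiblast-like states were compared with nascent mesoderm-like state 37, because no state took the primitive streak name. Among the epiblast-like states, state 3 also held streak genes, with T at 0.74 and Eomes at 0.67. Its Mesp1 level of 0.59 sets the upper end of the epiblast-like range below. State 37 was higher in Mesp1 (1.20 against a mean of 0.20 and a range of 0.018 to 0.59 over the 4 epiblast-like states), a transcription factor of the first mesoderm (chromosome 7, 79792241 to 79793788), and in the Nodal antagonist gene Lefty2 (1.12 against 0.12). Lhx1 (0.79 against 0.12), Fgf3 (0.71 against 0.057), Cyp26a1 (0.83 against 0.18), which degrades retinoic acid, and Fn1 (0.80 against 0.22) were higher as well. The epiblast-like states were higher in Utf1 (0.96 against 0.15), Cldn6 (0.74 against 0.16), Pim2 (0.88 against 0.31) and Trh (0.64 against 0.11). Nascent mesoderm markers were higher in state 37 in 5 of 10 cases, primitive streak markers in 3 of 9, and epiblast markers were lower in 2 of 12, where the mesoderm and epiblast lists named the states. In all 4 genes were higher in the epiblast-like states and 13 in state 37, 4 in total at 0.75 (SD of all differences 0.162).

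Presomitic mesoderm-like state 30 differed from nascent mesoderm-like state 37 in genes of trunk position. Of 9 measured Hox genes of paralogue groups 5 to 9, 6 were higher in state 30, such as Hoxc8 (0.79 against 0.00034) and Hoxb9 (0.77 against 0.0027), and all 3 Cdx genes, which act upstream of them, were higher, such as Cdx4 (0.80 against 0.019). The non-coding Hox cluster transcripts Hoxaas3 (1.17 against 0.0045) and Hoxb5os (0.84 against 0) and the segmentation clock gene Hes7 (0.78 against 0.17) were also higher. Reads of such antisense transcripts cannot be told from those of the overlapping coding genes unless strand was used, which the sources used here do not state. State 37 was higher in Mesp1 (1.20 against 0.13), Lefty2 (1.12 against 0.11), the Nodal co-receptor gene Tdgf1 (0.95 against 0.00027), Pou5f1 (1.10 against 0.21) and Eomes (0.62 against 0). In all 18 genes were higher in state 30 and 9 in state 37, 11 in total at 0.75 (SD of all differences 0.199).

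Somite-like state 18 was lower than state 30 in part of the Cdx and Hox genes. It was lower in all but 1 of the 3 Cdx genes by the 0.5 threshold, with Cdx2 at 0.043 against 0.79 and Cdx4 at 0.025 against 0.80, and in 5 of 9 Hox genes of groups 5 to 9, such as Hoxc8 (0.036 against 0.79). T, the brachyury gene of the streak and notochord, was at 0.028 against 0.62, and Hes7 at 0.20 against 0.78. Higher in state 18 were Meox1 (1.05 against 0.23) and Tcf15 (1.11 against 0.34), transcription factors of somite formation, Aldh1a2 (1.04 against 0.31), which makes retinoic acid, Arg1 (1.06 against 0.44) and Fst (0.88 against 0.37). In all 5 genes were higher in state 18 and 17 in state 30, or 5 in total at 0.75 (SD of all differences 0.168).

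Neuromesodermal progenitors feed both the spinal cord and the paraxial mesoderm, and states 26 and 31 were set against each. Against hindbrain and spinal cord-like state 39 they were higher in all 3 Cdx genes, with Cdx2 at 1.00 against 0.13 and Cdx4 at 0.84 against 0.14, in T (0.77 against 0.020), in the ligand genes Fgf8 (0.73 against 0.025) and Rspo3 (0.72 against 0.057), and in Nkx1-2 (0.72 against 0.13). State 39 was higher in Crabp1 (1.16 against 0.53), Sfrp1 (0.84 against 0.23), Pax6 (0.66 against 0.064), a regulator of neural progenitors, and the Notch target Hes5 (0.77 against 0.23). These were 13 and 5 genes, 1 in total at 0.75 (SD of all differences 0.153). Cdx2, Cdx4, T, Fgf8 and Nkx1-2 are markers that named states 26 and 31, and Crabp1 and Pax6 are markers that named state 39. These counts therefore follow partly from the naming. Against presomitic mesoderm-like state 30 only 5 genes passed, none of them at 0.75. Nkx1-2 (0.72 against 0.039), Hes3 (0.54 against 0.018) and Igfbp2 (0.75 against 0.24) were higher in the progenitor-like states, and Cited1 (0.55 against 1.23) and Pcdh19 (0.056 against 0.68) were lower (SD of all differences 0.125). Just under the threshold, the Notch ligand gene Dll1 stood at 0.14 against 0.63 in state 30, and the paraxial mesoderm factor Tbx6 at 0.20 against 0.66.

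Along the neural axis, forebrain and midbrain-like state 1 was higher than hindbrain and spinal cord-like state 39 in Dnmt3b (0.93 against 0.30), Pou5f1 (0.76 against 0.13), the anterior neural factor Hesx1 (0.61 against 0.0083), Pcsk1n (0.59 against 0.022) and Pim2 (0.60 against 0.076). Of these, 3 are among the 12 epiblast markers. State 39 was higher in Hoxaas3 (0.63 against 0.066), Hoxb5os (0.57 against 0.019), 1700011H14Rik (0.63 against 0.094) and Fgfbp3 (0.65 against 0.13). The head gene Otx2 was at 0.49 in state 1 and 0.011 in state 39, and Hoxd4 at 0.035 and 0.52, both just under the threshold. None of the 9 genes passed at 0.75 (SD of all differences 0.126), and state 1 lost its name when only markers of a single list were used.

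Surface ectoderm-like states 10 and 16 carried epithelial genes that the neural states 1 and 39 held low. The simple keratins Krt8 (1.17 against 0.20) and Krt18 (1.21 against 0.25), the tight junction genes Cldn6 (0.98 against 0.18) and Cldn7 (0.66 against 0.080), Epcam (0.94 against 0.26) and Wnt6 (0.78 against 0.019) were higher there. Of 11 genes of keratins and simple epithelium, 6 were higher in the surface ectoderm-like states, and of the 9 markers that named them, 5. The neural states were higher in the Wnt antagonist gene Sfrp1 (0.81 against 0.20) and Hes5 (0.67 against 0.077). In all 2 genes were higher in the neural states and 12 in the surface ectoderm-like ones, 4 in total at 0.75 (SD of all differences 0.160). With only markers of a single list, states 1, 10 and 16 had no name.

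Primitive blood-like states 9 and 22 were set against endothelium-like states 13, 32 and 36. State 36 is the least certain of these, since its nearest state was blood-like state 9 (r = 0.61), it was the highest for the blood markers Itga2b (0.64) and Nfe2 (0.50), and it lost its name under the mean list score. All 3 measured globins were higher in blood, Hba-a1 at 1.75 against 0.56, Hba-a2 at 1.48 against 0.21 and Hbb-bs at 1.11 against 0.28, as were all 4 measured genes of haem synthesis and the red cell membrane, with Alas2 at 0.89 against 0.11. The red cell factor Klf1 was at 0.85 against 0.15. Hba-a1 (chromosome 11, 32283511 to 32284465) and Hba-a2 (32296489 to 32297298) are near-identical copies, so the division of reads between them is uncertain. The endothelium-like states were higher in Mest (1.10 against 0.24), Vim (0.91 against 0.090), Kdr (0.74 against 0.016), the receptor for vascular endothelial growth factor, Ramp2 (0.77 against 0.034) and Fn1 (0.94 against 0.23). In all 21 genes were higher in the endothelium-like states and 19 in blood, 8 in total at 0.75 (SD of all differences 0.211), and the share higher in the endothelium-like states was 52.5%, or 34.4% after centring each state on its median.

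The blood-like states themselves did not part by this measure, and no gene differed by 0.5 between them. The largest difference was in Xist, at 0.45 in state 22 and 0.79 in state 9, ahead of Fn1 (0.079 against 0.37), Hbb-bs (1.22 against 1.00) and Tspan33 (0.31 against 0.53). The differences of all genes had an SD of 0.0352.

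Contractile genes separated heart tube-like states 6 and 21 from pharyngeal mesoderm-like state 34. Of 14 measured sarcomere genes 11 were higher in the heart states, with Myl7 at 1.34 against 0.15 (chromosome 11, 5896637 to 5898782), Myl4 at 1.13 against 0.13, Tnnt2 at 1.06 against 0.073 and Tnni1 at 1.03 against 0.051. Many sarcomere genes, these among them, are markers that named the heart states. State 21 carried much of the means. In state 6, Myl7 stood at 0.93 and Tnnt2 at 0.59, but Actc1 at 0.56, Tnnc1 at 0.29 and Ttn at 0.17. In state 34 Actc1, Tnnc1 and Ttn stood at 0.29, 0.039 and 0.021. State 34 was higher in Fst (0.82 against 0.10), Ebf1 (0.67 against 0.028), the matrix genes Lum (0.60 against 0.048) and Col3a1 (0.67 against 0.14), and Ptn (0.91 against 0.39). In all 26 genes were higher in the heart states and 5 in state 34, 7 in total at 0.75 (SD of all differences 0.201). State 34 lost its name when the list score was a rank.

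The heart states stood far apart from each other. State 6 correlated nearly as well with unnamed states 5 (r = 0.511) and 20 (0.498) as with state 21 (0.534). Only 7 of its 12 measured heart tube markers were raised, and its second list was lateral plate mesoderm (score 0.94 against 1.64). Its Myl7 level of 0.93 was close to the 0.88 of nascent mesoderm-like state 37, so its heart tube likeness is partial. State 21 was higher than state 6 in all 14 sarcomere genes, with Myl3 at 1.27 against 0.074, Ttn (titin) at 1.32 against 0.17, Actc1 at 1.67 against 0.56, and the myosin heavy chain genes Myh6 at 1.08 against 0.021 and Myh7 at 1.09 against 0.059. State 6 was higher in 1 gene, Arg1 (0.72 against 0.12). It also held Aldh1a2 at 0.51 against 0.051, Foxf1 at 0.47 against 0.076 and Hoxb1 at 0.43 against 0.051, all under the threshold. State 21 was higher in 36 genes, and the total of 37 was 21 at 0.75 (SD of all differences 0.224).

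Extraembryonic mesoderm-like states 15 and 41 were compared with unnamed state 5, whose nearest state was state 15 (r = 0.66), since no state took the allantois name. The fibrillar matrix genes were higher in 5 of 8 cases in states 15 and 41, among them Postn (periostin, 0.80 against 0.017), Lum (1.04 against 0.010) and Col3a1 (0.77 against 0.054). The smooth muscle genes Acta2 (1.41 against 0.64) and Tagln (1.08 against 0.38) and the imprinted gene Nnat (1.09 against 0.33) were higher too. State 5 was higher in Amot (0.90 against 0.29), the imprinted placental gene Phlda2 (1.52 against 0.95) and Cdx2 (0.71 against 0.16). In all 21 genes were higher in states 15 and 41 and 3 in state 5, 6 in total at 0.75 (SD of all differences 0.178). State 5 took the differentiated trophoblast name when the list score was a rank. That list had 4 measured markers, of which Hand1 and Plac1 are also extraembryonic mesoderm markers. By the main score its best list was lateral plate mesoderm (1.93). It stayed unnamed because its leading genes held more extraembryonic mesoderm markers (3) than lateral plate markers (1).

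Primordial germ cell-like state 27 kept Pou5f1 at 1.17, close to the epiblast-like states (1.18 to 1.22), but differed from them in other genes. Dppa3 was at 0.76 against a mean of 0.011 (chromosome 6, 122626410 to 122630272), Dnd1, needed for germ cell survival, at 0.80 against 0.092, Ifitm3 at 1.33 against 0.28 and Ifitm1 at 1.37 against 0.31. Cdx2 (0.92 against 0.15; chromosome 5, 147300805 to 147307270) and Msx1 (0.85 against 0.12) were higher as well. The de novo DNA methyltransferase gene Dnmt3b was lower (0.20 against 1.28), with Pim2 (0.080 against 0.88), Otx2 (0.020 against 0.54), Slc7a3 (0.041 against 0.56), Pou3f1 (0.053 against 0.56) and Igfbp2 (0.40 against 0.97). In all 16 genes were higher in state 27 and 6 in the epiblast-like states, 6 in total at 0.75 (SD of all differences 0.185).

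Node and notochord-like states 23 and 38 were higher than gut endoderm-like state 7 in T (1.28 against 0.35), Noto (0.73 against 0.010), a node transcription factor, Ppp1r1a (1.04 against 0.18) and Aplnr (0.76 against 0.064), and in Cfap126 (0.72 against 0.032) and Pifo (0.71 against 0.051). State 38 carried the means of Cfap126 and Pifo, which both stood at 1.14 there but at 0.30 and 0.27 in state 23. State 7 was higher in Spink1 (1.47 against 0.46), Trh (1.21 against 0.33), Sox17 (0.67 against 0.046), a factor of definitive endoderm, and Apela (0.99 against 0.37), the ligand of the receptor that Aplnr encodes. In all 29 genes were higher in the node states and 15 in state 7, 5 in total at 0.75 (SD of all differences 0.219). State 38 was higher than state 23 in Foxj1, a regulator of motile cilia, at 1.13 against 0.093 (chromosome 11, 116330704 to 116335399), in Tppp3 at 1.24 against 0.12 and in Dynlrb2 at 1.11 against 0.10. State 23 was higher in Tgfb2 (0.71 against 0.14), Vim (1.05 against 0.48) and the cartilage collagen gene Col2a1 (0.60 against 0.054), which notochord also makes. The counts were 32 and 4 genes, 18 in total at 0.75 (SD of all differences 0.214).

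Gene groups that mark position along the body peaked in the posterior states. The 9 measured Hox genes of groups 5 to 9 had their highest median in neuromesodermal progenitor-like state 31 (0.76, against a median of 0.023 over states), followed by presomitic mesoderm-like state 30 (0.58), and 7 of the 9 were highest in state 31. The 7 genes of groups 1 to 4 had a flatter profile, with medians of 0.47 in state 31, 0.45 in state 30 and 0.40 in state 26. Among the Cdx genes Cdx1 was highest in state 26 (1.16), and Cdx2 (1.01) and Cdx4 (0.98) in state 31. Cdx2, Cdx4, Hoxb9 and Hoxc9 are also markers that named states 26 and 31, so these peaks follow partly from the naming. Hoxb6 departed from its group and was highest in extraembryonic mesoderm-like state 41 (0.61), followed by state 5 (0.50). The somite clock and Notch group was highest in presomitic mesoderm-like state 30 (median 0.63), where 4 of its 5 genes peaked. Its members Hes7, Dll1 and Dll3 are also markers that named state 30, so this peak follows partly from the naming. The retinoic acid group was highest in somite-like state 18 (0.47; state 39 by the mean of its members), where Aldh1a2 reached 1.04, while Cyp26a1 peaked in state 31 (0.87).

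**Figure D4:**
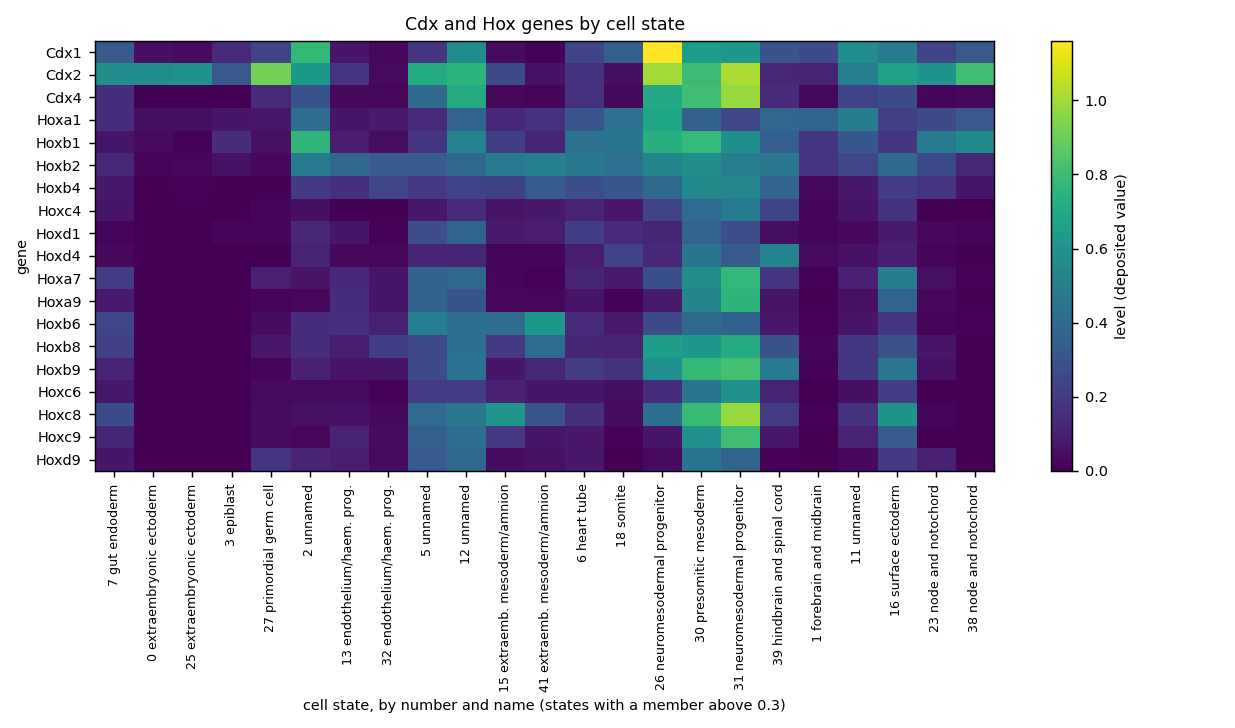
Level of the measured Cdx and Hox genes (rows) in the cell states where any of them exceeds 0.3 (columns, in the order of an average-linkage tree), with colour giving the deposited value. The Hox genes of groups 5 to 9 are brightest in states 30 and 31, where their medians are 0.58 and 0.76.

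Signalling genes peaked in different states. Of the 6 Wnt ligand genes, Wnt6 was highest in surface ectoderm-like state 16 (1.06), Wnt7b in extraembryonic ectoderm-like state 0 (0.51) and Wnt2 in heart tube-like state 21 (0.74). Among 4 Wnt antagonist genes, Sfrp1 peaked in unnamed state 24 (0.90) and Frzb in nascent mesoderm-like state 37 (0.64). Fgf8 was highest in primordial germ cell-like state 27 (0.90), Fgf5 in epiblast-like state 17 (0.66), Fgf17 in state 31 (0.72) and Fgf3 in endothelium-like state 13 (0.77). Bmp4 (0.97) and Bmp2 (0.71) peaked in extraembryonic mesoderm-like state 41, and Lefty2 in state 37 (1.12). The antagonist gene Nog was highest in parietal endoderm-like state 14 (0.72), ahead of node-like state 23 (0.69).

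All 14 sarcomere genes were highest in heart tube-like state 21 (median 1.36, against 0.26 in state 6), and 13 of 14 plasma protein genes in visceral endoderm-like state 40 (median 1.27), the exception being Mttp in state 29 (0.85). Many members of these groups, and of the basement membrane and globin groups below, are markers that named the states. Their peaks therefore follow partly from the naming. The 7 endocytosis genes had medians of 1.11, 1.07 and 1.02 in states 40, 29 and 4. All 5 basement membrane genes were highest in parietal endoderm-like state 14 (median 1.35), and 6 of 8 fibrillar matrix genes in extraembryonic mesoderm-like state 41 (median 0.99). The 3 globins and 3 of the 4 haem and red cell membrane genes were highest in blood-like state 22, although state 9 led the haem group without its most variable member. The 11 genes of keratins and simple epithelium had their highest median in gut endoderm-like state 7 (0.88), although Krt8 was highest in extraembryonic mesoderm-like state 41 (1.43).

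Pluripotency genes were spread over several lineages. The 9 measured genes had their highest median in epiblast-like state 17 (0.48), but only Dppa5a was highest there (0.72). Dppa5a, Pou5f1 and Nanog are also markers that named the epiblast-like states, so this peak follows partly from the naming. Pou5f1 peaked in epiblast-like state 19 (1.22), Nanog in state 3 (0.32), Sox2 in unnamed state 24 (0.67), Zfp42 in extraembryonic ectoderm-like state 25 (0.58), Klf4 in parietal endoderm-like state 14 (0.82) and Klf2 in endothelium-like state 32 (0.77). Of the DNA methylation genes, Dnmt3b (1.35, state 8) and Dnmt3a (0.72, state 17) were highest in epiblast-like states, and Dnmt3l, their cofactor, in extraembryonic ectoderm-like state 0 (0.57).

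Transcripts that were high in visceral endoderm-like and blood-like states also lay above 0 in states of other types. Among the 37 states outside endoderm, Ttr ranged from 0.16 to 0.35 (median 0.24), against 1.60 to 1.79 in the visceral endoderm-like states, and Rbp4 from 0.099 to 0.37 against 1.36 to 1.75. Afp (0.010 to 0.079) and Apoa4 (0.020 to 0.052) were lower outside endoderm, and Apom ran from 0.056 to 0.15. Hba-a1 ranged from 0.0061 to 0.60 in 34 states outside blood, endoderm and state 36, where it stood at 0.81, with a median of 0.43 against 1.72 to 1.78 in blood. Hba-a2 (median 0.13, highest 0.28) and Hbb-bs (median 0.14, highest 0.64) had lower medians there.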

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

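Centring each state on its median and leaving out each state in the globin test were added only after the results had been seen. No paired analysis was possible because the table has no column per library and every result comes from no test. State names held in most cases, with 35 of the 36 kept when the list score was a mean (state 36 lost its name) or a rank (state 34 lost its name, and unnamed states 5 and 12 became differentiated trophoblast-like), and 32 when only markers of a single list were used (states 1, 10 and 16 lost theirs, 28 became extraembryonic ectoderm-like, and unnamed state 24 became hindbrain and spinal cord-like). The alternatives for similarity gave 13 to 15 mutual pairs, and the nearest state stayed the same for 34 (levels not centred) to 41 of 42 states. Ward linkage kept 14 of the 16 leaf pairs of the tree and lost those of states 6 and 21 and of 30 and 31. Centring each state on its median left all totals within 1.5 times, but the share higher in the endothelium-like states than in blood fell from 52.5% to 34.4%, which turned the balance. The stricter threshold of 0.75 lowered the count of differing genes by its own construction. The totals became 15 (visceral against gut endoderm), 46 (parietal against visceral), 7 (extraembryonic ectoderm against trophoblast), 4 (epiblast against nascent mesoderm), 11 (presomitic against nascent mesoderm), 5 (somite), 1 (neuromesodermal progenitor against spinal cord), 0 (against presomitic mesoderm), 0 (forebrain against hindbrain), 4 (neural against surface ectoderm), 8 (endothelium against blood), 7 (heart tube against pharyngeal mesoderm), 21 (between heart states), 6 (extraembryonic mesoderm against state 5), 6 (germ cell against epiblast), 5 (node against gut) and 18 (between node states). With only genes whose highest level lay above the median of all genes, which tests fewer genes, the progenitors differed from presomitic mesoderm in 3 genes and forebrain from hindbrain in 5. Of the 892 leading combinations 88 remained against the next highest state, and the cause was not tested, while there were 1163 against the median of the others and 724 with the same filter on genes. The state leading each of the 23 gene groups stayed the same for 18 by the mean and 17 without the most variable member. Differences after a back-transform were not run, because the base is not recorded, and leaving out states next to the free RNA sources removed no state, so it gave no value. Unknown cell numbers per state limit all small differences.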

Other observations

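The tests of a sex difference, of long transcripts, of the length trend, of free visceral endoderm RNA and of the globin sources were chosen or written only after the results they measure had been seen.

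The 6 unnamed states each had leading genes from the fixed lists. State 2 had Mesp1 at 0.90, the imprinted gene Phlda2 at 1.45, Aldh1a2 at 0.74, Pou5f1 at 0.96 and Cdx1 at 0.77, and its nearest state was nascent mesoderm-like state 37 (r = 0.71). State 12 combined Hoxaas3 (0.86) and Cdx4 (0.71) with Phlda2 (1.41) and Spin2c (0.75). State 5 combined Spin2c (1.03) with Hand1 (0.97), a factor of extraembryonic and lateral mesoderm, and the hindlimb factor Pitx1 (0.70). Pitx1 is also on the allantois list, which had too few measured markers to give a name. State 20 held Prrx2 (0.81), the somite gene Tcf15 (0.75), Fst (0.84) and the pharyngeal gene Tbx1 (0.51), and was nearest to pharyngeal mesoderm-like state 34 (r = 0.75). State 11 had Crabp2 at 1.03, Ptn at 0.95, Stmn2 at 0.61 and Hesx1 at 0.44 beside forebrain and midbrain-like state 1, and state 24 had Ptn at 1.17, Crabp1 at 1.21, Sfrp1 at 0.90 and Sox2 at 0.67 beside hindbrain and spinal cord-like state 39. The best list of state 24 was nevertheless forebrain and midbrain (score 2.35, against 1.85 for hindbrain and spinal cord). It stayed unnamed because its 10 leading genes held 3 hindbrain and spinal cord markers and 1 of forebrain and midbrain.

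Imprinted genes, of which 10 were measured, had their highest median in extraembryonic mesoderm-like state 41 (0.82), where Dlk1 reached 1.34 and Igf2 0.96. Phlda2 (1.60) and Ascl2 (0.88), which restrain or specify placental cells, were highest in differentiated trophoblast-like state 28, and Peg10 in visceral endoderm-like state 40 (1.13). The X-linked homeobox gene Rhox5 was highest in extraembryonic ectoderm-like states 0 (1.39) and 25 (1.38).

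Low Xist in states 25, 19, 35 and 11 beside close states with high Xist was weighed first. Over 666 genes outside the X chromosome the differences of these pairs resembled each other, with a median correlation of 0.404 (range 0.279 to 0.498 over 6 combinations) against 0.041 and at most 0.276 among 11 other pairs, but autosomal effects of sex could be shared too, so sex as the whole cause was left open. The pairs also shared lower levels of long transcripts (rho = -0.484, -0.541 to -0.418), a trend that predicts an Xist difference of only -0.061 (2 residual SDs giving -0.147 to 0.025) against -0.665 observed, so transcript length does not account for its size. For lower detection of all genes, the share of genes that were lower (42.3% to 67.4%) met the limit set beforehand against it. In the 11 other pairs that share ran from 24.3% to 79.1%, so it was not fixed, but the unknown normalisation could still shift it. States 25, 19 and 35 held more zeros (99, 19 and 38) than states 0, 8 and 33 (0, 5 and 6), although states 11 and 1 both held 0. Zeros also depend on the unknown number of cells in a state. Median levels were lower in states 25 (0.024 against 0.029) and 35 (0.045 against 0.049), but not in 19 (0.035 against 0.032) and 11 (0.058 against 0.053). Lower detection was therefore left open as well. Blood-like states 22 and 9, counted among the other pairs because Xist stood at 0.45 in state 22, also had Xist as their largest difference and a length trend (rho = -0.239). Some autosomal genes shared by the 4 pairs recurred there. Elavl1 and Otub1 were higher in all 4 low Xist states and in state 22 (Elavl1 at 0.78 against 0.69 in state 9). Igsf3 and Nrip1 were lower in all 4 and in state 22 (Igsf3 at 0.076 against 0.23). The largest mean rise was in the globin gene Hbb-bs (0.151), but it was not shared by all 4 pairs (-0.114 to 0.371). Hbb-bs was also higher in state 22 (1.22) than in state 9 (1.00), and outside blood it was highest in state 25 (0.64). Rps27rt rose by similar amounts in all 4 pairs (0.112 to 0.144), and mt-Atp8 fell in all 4 (-0.232 to -0.159). These differences lay under 0.5. Whether a library or free RNA difference underlies them was not tested. Sex, library and stage could not be separated in a table without a column per library.

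Transcripts of visceral endoderm lay above 0 in every state. Over 58 genes that define those states, the lowest level outside endoderm followed the level within it (rho = 0.843), as free RNA from broken endoderm cells could leave, although the idea came from the same values. Over 34 states Ttr followed Rbp4 (rho = 0.656), Afp (0.576) and Apom (0.404), and Rbp4 followed Afp (0.801). Apom did not follow Rbp4 (-0.057) or Afp (-0.195), so free RNA from visceral endoderm was left open. Afp and Rbp4 also followed the blood gene Hba-a2 (0.929 and 0.816). That does not count against free RNA, because blood cells could release it too, but it is not particular to visceral endoderm. Heart genes, the only other type compared, argue against a floor of the same height for the leading genes of any cell type. Their median floor was 0.029 times that of visceral endoderm genes. The floors of single genes overlapped, with the highest heart floor at 0.0486 (Myl7) and the lowest endoderm floor at 0.0102 (Afp). A floor that differs between genes or cell types could therefore not be excluded. Low true expression of Ttr or Rbp4 in other cells remains possible, and no biological explanation was tested.

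Globin transcripts outside blood and endoderm were the last pattern. Over 34 states, state 36 left out, Hba-a2 and Hbb-bs were unrelated (rho = 0.033, -0.058 to 0.083 without each state in turn), but Hba-a1 followed Hba-a2 (0.838) and partly Hbb-bs (0.441), so a single source of free red cell RNA was left open. Hba-a1 was explained to 96.0% by both genes together and to 70.4% and 20.2% by each, a gain of 25.6 percentage points (15.9 to 27.3 without each state in turn). The gain met the limit set for 2 sources that differ in their globins. It follows by arithmetic from the pairwise correlations already seen, so it gives no separate evidence for 2 sources. Hbb-bs is also the only measured gene of the 15 in the maternal immune and adult blood group, so embryonic and maternal sources could not be told apart. Because Hba-a1 and Hba-a2 are near-identical, reads shared between them could produce part of this relation, and the states are not independent samples. No biological explanation was tested.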
